A study of Mus musculus with 2 samples.

How the data were processed

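H3K27ac was measured by chromatin immunoprecipitation and sequencing in unstimulated macrophages grown from the bone marrow of C57BL/6J mice. Per the labels, the libraries are 2 biological replicates from separate biosamples that carry the same donor entry, each started from 10 ng of DNA with a size range of 350 to 480, whose unit the labels do not give. Since the donor entry is shared, the spread between replicates may leave out differences between animals. Stage, age and sex were unknown or not collected, per the labels.

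The authors deposited 4 peak lists on mm10. Per the text files deposited with the samples, each replicate has a list of pseudoreplicated peaks made from its own alignments, and a replicated list and a pooled pseudoreplicated list were made from the alignments of both replicates together. Peaks were thus called per sample in the replicate lists and on pooled samples in the other lists, whose values are the authors' own and have no SD or n. The deposited fold of each peak is a linear ratio over control or background, and the deposited q-value of each peak is on a −log10 scale. The aligner, the peak caller and their settings were not given in the sources used here. The read depth behind the lists was not given in those sources either, so a region without a peak was below the authors' threshold in that library and need not lack H3K27ac. Folds were not scaled between lists by any step recorded in the labels, and were used to describe, rank or filter peaks within a list. No list held overlapping entries.

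Positions are 1-based on GRCm38 patch 6, the build of mm10, with gene models from GENCODE mouse release M21. Peaks of a replicate were called shared when they overlapped a peak of the other by at least 1 bp, and the share was set beside 100 circular shifts of the other list within each chromosome. Peaks were ranked by fold within their list and divided into 10 equal bins. Each peak was placed by its midpoint as promoter (within 1 kb of a start of any protein-coding transcript), exon, intron or intergenic. A gene was called marked when a peak of each replicate overlapped the 1 kb on either side of any of its annotated starts, among 21938 protein-coding genes and 93513 starts.

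The tests, the gene lists and the alternatives were fixed before the data were examined, apart from those named as chosen later. The 26 gene lists cover macrophage identity, housekeeping, cell cycle, lysosome, cholesterol, NF-kB, inflammatory, interferon and interleukin-4 responses, tissue-resident macrophages, and markers of other blood lineages and tissues. Of their names, 6 matched no protein-coding symbol of the annotation and were not used here, and 31 of the 644 genes stand in more than 1 list. Each list was set against all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Distal peaks were replicate 1 peaks over 1 kb from every protein-coding start that a replicate 2 peak overlapped, and their mean number within 25 kb of the 5′ end was tested against 10000 random lists of the same size and number of marked genes (two-sided permutation test, adjusted over the lists). Distal peaks of the replicated list within 10 kb of each other were joined into clusters. Sequences of 500 bp around the midpoints of distal peaks were compared with sequences 5 kb to either side outside all peaks, for 12 words read on both strands, and each ratio was ranked among up to 1000 reorderings of the word's letters (one-sided exact test by rank, adjusted over the words). Genes and peaks are not replicates, so these p values describe the 2 libraries. Intervals for shares are 95% Wilson intervals and cover counting error only.

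Genes were named by a rule: from each list the 2 marked genes with the highest fold in the replicated list (up to 4 where under 50% were marked) and the first 2 in alphabetical order without a promoter peak in either replicate; the 10 genes with the highest promoter fold of all; the genes of the 10 longest clusters; listed genes with a promoter peak in 1 replicate alone that lay in the upper 50% of that list by fold; and Spi1, Csf1r, Cebpa, Cebpb, Adgre1, Itgam, Cd68, Lyz2, Actb, Gapdh, Tnf, Il6, Ifnb1 and Xist. The Y-linked genes were fixed with the sex chromosome comparison, and genes that overlap a cluster were named with it. Some genes that the rule takes, and the results that need their names, are not reported here.

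The alternatives were an overlap of 50% of both peaks, a −log10 q of at least 5, the 20000 peaks with the highest fold, redrawn shifts, promoter windows of 2.5 kb and 500 bp, the gene's 5′ end alone, each list made from both libraries, lists without genes that share a promoter, a distance of 100 kb, unmatched random lists, joining within 5 kb, sequences of 200 bp, and each replicate alone. Random lists matched on the decile of promoter CpG content, distal peaks counted for the nearest gene alone, and each replicate alone for the number of peaks and the sex chromosomes were added after seeing the data.

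The steps were tested on simulated data with the real genes. In simulated replicate lists 86.9% of peaks had been placed in both lists and 86.9% were found shared. The same 40 unchanged lists of 30 genes were run through both tests, and 0 were called at promoters and 0 near distal peaks, and the 2 planted promoter lists and the 1 planted distal list were recovered. A PU.1 word planted in 10% of random sequences was recovered, with 0 other words called. The unchanged lists were random genes that all had the same chance of being marked, and unplanted distal peaks were placed at random along the chromosomes. The random sequences held the bases in equal shares. The simulation therefore does not show how the tests behave where lists differ in CpG content or peaks differ from flanks in base composition. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.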

Results

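The series profiled H3K27ac, an acetylation of histone H3 that marks active promoters and enhancers, by chromatin immunoprecipitation and sequencing in mouse macrophages grown from bone marrow and left without stimulation. The cells came from the C57BL/6J strain and formed a single group of 2 biological replicates, so the comparisons below set the replicates against each other, promoters against the rest of the genome, and lists of genes against all other genes. Replicate 1 gave 29543 peaks and replicate 2 gave 29345, a mean of 29444 ± 140 (SD, n = 2). They covered 38.3 and 39.9 Mb of GRCm38, with a median width of 898 and 962 bp. The read depth of the libraries was not given in the sources used here. The fold of each peak is the authors' own value and describes or ranks peaks within its own list; where a pair of folds is given, the first is from replicate 1 and the second from replicate 2.

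The highest promoter peaks included those of a polyubiquitin gene, of macrophage genes and of a lysosomal protease. The polyubiquitin gene Ubb had the highest fold in the authors' pooled replicated list, at 60.9 (52.3 and 56.5 in the replicates), followed by Ctsb, which encodes the lysosomal protease cathepsin B, at 58.0 (53.3 and 53.3). Sirpa, an inhibitory receptor of myeloid cells, reached 57.5 (54.2 and 51.6), and Spi1, which encodes the myeloid transcription factor PU.1, reached 54.9 (50.8 and 50.3). The 10 highest also included the retinol metabolism gene Dhrs3 (56.9), Arhgap22 (55.3), and Brd2 and H2-DMa, which share a peak (54.6). Brd2 and H2-DMa each have a start of another protein-coding gene within 1 kb, so the peak cannot be given to either gene. The reference genes Actb and Gapdh had folds of 44.7 and 45.3, and of 30.5 and 23.1.

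The replicates shared most of their peaks. Of the replicate 1 peaks, 91.3% (26965 of 29543) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks, 88.6% (25999 of 29345) overlapped a replicate 1 peak. Lists shifted at random along each chromosome overlapped in 2.83% of replicate 1 peaks on average, with a range of 2.43 to 3.55% over 100 shifts. Peaks of both replicates had 79.4% of their covered bases in common. Across the 26965 shared peaks, which are not independent replicates, the folds had a Spearman correlation of 0.868 and a Pearson correlation of log2 values of 0.883. When an overlap of 50% of both peaks was required, the mean share fell from 89.9% to 78.4%.

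Sharing followed the rank of a peak in its list. Of 10 equal bins ranked by fold, all peaks of the upper 4 bins of replicate 1 were found in replicate 2, against 56.3% (95% Wilson interval 54.5 to 58.0) of the lowest bin. In the opposite direction 49.1% (47.3 to 51.0) of the lowest bin of replicate 2 were found in replicate 1. The 2578 peaks seen in replicate 1 alone had a median fold of 3.78 and a median width of 431.5 bp, against 7.57 and 983 bp for shared peaks of the same list. The 3346 peaks of replicate 2 alone had a median fold of 3.85, and the highest fold among them was 8.71. Most peaks of a single replicate were in the authors' replicated list, which was made from both libraries together: 83.4% of those of replicate 1 and 80.1% of those of replicate 2. These intervals cover counting error only.

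**Figure D1:**
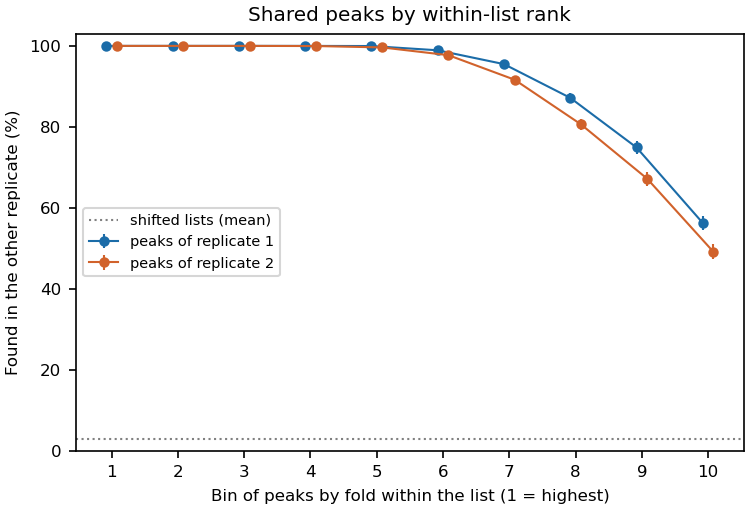
Share of peaks (%, vertical axis) of each replicate found in the other, for 10 equal bins of peaks ranked by the authors' fold within the list (horizontal axis, 1 is the highest); bars are 95% Wilson intervals and the dotted line is the mean over shifted lists. The share is 100% in bins 1 to 3 of both replicates and ends at 56.3% for replicate 1 and 49.1% for replicate 2.

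H3K27ac peaks lay at promoters more often than shifted peaks did. With a promoter defined as 1 kb on either side of a start of a protein-coding transcript, 37.2% ± 0.343 of peaks (SD, n = 2) had their midpoint there, against 3.95% of shifted peaks, a ratio of 9.42. Exons held 2.65% ± 0.0270 of the peaks, introns 33.2% ± 0.207 and intergenic sequence 26.9% ± 0.163, against 2.78%, 34.5% and 58.7% of shifted peaks. In each of the 2 replicates the promoter share lay above the highest of 100 shifts (4.62% and 4.69%) and the intergenic share below the lowest (56.5% and 56.5%). A total of 8633 of 21938 protein-coding genes (39.4%) had a promoter peak in both replicates and are called marked below, while 244 had one in replicate 1 alone and 497 in replicate 2 alone.

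Nearly all genes that define macrophages were marked. Of 39 macrophage identity genes, 37 (94.9%) were marked, in each replicate the same number, against 39.3% of all other genes (Fisher's exact test, two-sided, adjusted p = 2.4e-12). Besides Sirpa and Spi1 they included Csf1r, the receptor for the growth factor that sustains macrophages (48.4 and 35.7), Cd68, a lysosomal glycoprotein (46.5 and 45.3), Lyz2, lysozyme (26.9 and 22.4), Adgre1, which encodes the F4/80 antigen (25.3 and 22.1), Itgam, which encodes CD11b and has another start within 1 kb (21.5 and 21.4), and the transcription factor gene Cebpa (13.4 and 13.7). The 2 genes without a promoter peak in either replicate were Adgre4 and Cebpb. Cebpb, a transcription factor gene, had its nearest peak 1141 bp downstream of the 5′ end in replicate 1 (fold 14.5) and 1143 bp downstream in replicate 2 (fold 14.8), just outside the window, and the replicated list had a weak peak within the window (fold 4.36). The sequence within 500 bp of the Cebpb 5′ end had a GC content of 75.8%.

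Spi1 and Csf1r each carried several peaks along the gene. Spi1 spans 91082390 to 91115756 of chromosome 2 on the forward strand, and its promoter peak in replicate 1 ran from 91080138 to 91088801, a width of 8664 bp that reached into an intron. A further peak in a Spi1 intron, at 91096135 to 91099719, had a fold of 38.7 in replicate 1 and 44.2 in replicate 2. Csf1r spans 61100598 to 61132149 of chromosome 18 on the forward strand. Its highest peak in replicate 1, from 61103445 to 61110343, had its midpoint in an intron 6296 bp from the 5′ end, and the replicated list merged it with the peak at the 5′ end into a region of 11333 bp (fold 50.6). Another Csf1r intron held a peak with folds of 23.6 and 24.5.

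**Figure D2:**
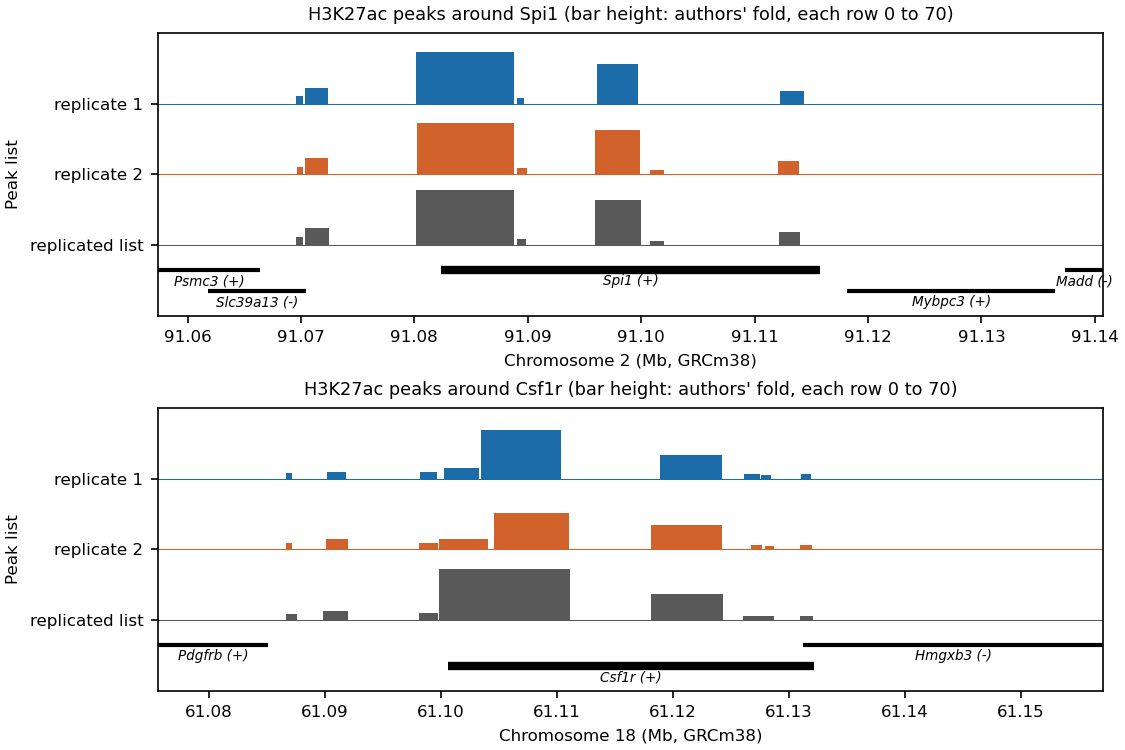
H3K27ac peaks of replicate 1, replicate 2 and the authors' replicated list around Spi1 (chromosome 2, upper panel) and Csf1r (chromosome 18, lower panel), with position in Mb on the horizontal axis, bar height as the authors' fold within each list on a scale of 0 to 70, and protein-coding genes as black lines with their strand. In each replicate, the tallest bar of the upper panel is the Spi1 promoter peak (50.8 and 50.3). That of the lower panel is the Csf1r peak that begins inside the gene (48.4 and 35.7). In the replicated list the tallest bars are 54.9 for Spi1 and 50.6 for Csf1r.

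Housekeeping, NF-kB, lysosome, cholesterol and cell cycle genes were also marked more often than other genes. All 30 housekeeping genes were marked (adjusted exact p = 4.5e-12), as were 50 of 51 genes of NF-kB signalling and pattern recognition (98.0%, adjusted exact p = 4.2e-18), with Bcl3, a nuclear IkB protein (43.7 and 45.6), and Tlr4, the lipopolysaccharide receptor (40.6 and 43.1), at the top. Of the lysosome and phagosome genes 37 of 38 were marked (97.4%, adjusted exact p = 3.0e-13), led by Ctsb and by Psap, a precursor of sphingolipid activators (44.2 and 42.4). Of the cholesterol and lipid genes 30 of 32 were marked (93.8%, adjusted exact p = 6.8e-10), including the cholesterol esterifying enzyme gene Soat1 (37.2 and 36.5). Cell cycle genes were marked in 24 of 26 cases (92.3%, adjusted exact p = 8.7e-08), with Birc5, which encodes survivin (23.7 and 24.4), and the centromere gene Cenpa (21.7 and 18.1) highest; replicate 2 alone had peaks at all 26. The shares in each replicate lay above the other genes for all of these lists. The members without a peak in either replicate were Traf6, a signalling adaptor with its nearest peak 20018 bp away in replicate 1; Atp6v0d2, a proton pump subunit; Scap, the escort protein of sterol-regulated transcription factors, with its nearest peak 27087 bp away; and Fabp4, a fatty acid binding protein that had a promoter peak only in the lists made from both libraries (fold 3.99).

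Many genes of inflammatory and interferon responses carried promoter H3K27ac although the cells had not been stimulated. Of 36 genes of the rapid inflammatory response, 28 (77.8%) were marked, 29 in replicate 1 and 28 in replicate 2 (adjusted exact p = 1.1e-05), among them Zfp36, which encodes the RNA decay factor tristetraprolin (50.3 and 48.4), Nfkbid, a nuclear IkB protein (43.5 and 42.7), and the cytokine gene Tnf (37.0 and 37.5). Of 36 interferon stimulated genes, 31 (86.1%) were marked in each replicate (adjusted exact p = 4.0e-08), led by Irf9, a subunit of the interferon-activated transcription factor (25.6 and 30), and the tetherin gene Bst2 (26.95 and 27.5). Of 28 genes of the delayed inflammatory response, 8 (28.6%, 95% Wilson interval 15.3 to 47.1) were marked, and the difference from other genes did not pass the test (adjusted exact p = 0.39). The marked ones included the chemokine genes Ccl12 (21.5 and 26.8), Ccl7 (16.9 and 19.7) and Ccl2 (11.5 and 12.1), and Ptges, prostaglandin E synthase (21.5 and 23.0). The Ccl2 peaks with these folds do not overlap, lying at 82034302 to 82035394 in replicate 1 and 82035493 to 82037502 in replicate 2. The cytokine genes Il6 and Ifnb1 had no promoter peak in either replicate, nor did Acod1, which makes itaconate, or the chemokine genes Cxcl1, Cxcl2, Cxcl9, Cxcl10, Ccl17 and Ccl22. Cxcl2 had a weak peak over its 5′ end in the replicated list (fold 3.15). The nearest peaks of Il6 were 23042 bp away in replicate 1 and 59600 bp away in replicate 2, while Cxcl10 had a peak 4078 bp upstream with folds of 16.4 and 13.1. Whether the classes of response genes differ from each other was not tested, and their lists differ in promoter CpG content. Random lists matched on it, a comparison chosen after seeing the data, were marked in 17.5% for delayed, 42.5% for rapid and 23.3% for interferon stimulated genes. The delayed share of 28.6% lay above its matched lists without passing that test either (adjusted permutation p = 0.257).

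Lists that stand for polarised or tissue-resident macrophages did not pass the test against other genes at promoters. Of 21 interleukin-4 response genes 10 (47.6%) were marked in both replicates and 12 in replicate 1 (adjusted exact p = 0.52), including Stat6, the transcription factor activated by interleukin-4 (41.1 and 42.6), Il4ra, the receptor chain (26.2 and 27.99), Mrc1, the mannose receptor (24.3 and 24.8), and Clec10a (12.5 and 18.8). At Pdcd1lg2, an immune checkpoint ligand of this list, a peak of replicate 1 (fold 16.5) reached the promoter window. The replicate 2 peak that overlaps it lay outside the window, so this is no difference in the presence of a peak. Of the microglia genes 7 of 14 were marked (adjusted exact p = 0.46), with the purinergic receptor gene P2ry13 (27.9 and 30.7) and Mef2c (28.4 and 25.8) at the top, while Olfml3 and Sall1, a transcription factor gene of microglia, had none. Of the liver macrophage genes 7 of 15 were marked (adjusted exact p = 0.60), including the sterol receptor gene Nr1h3, with another start within 1 kb (27.7 and 18.9), Hmox1, heme oxygenase (18.2 and 21.8), Cdh5 (18.2 and 16.4) and Id3 (17.2 and 13.6), but not C6 or Cd5l. Of the lung and peritoneal macrophage genes 4 of 20 were marked (adjusted exact p = 0.14), namely Siglecf (11.1 and 10.7), Icam2 (9.12 and 8.71), Pparg (6.45 and 6.62) and Cd9 (5.51 and 6.54), while Alox15 and Car4 had no peak. These adjusted p values are also from Fisher's exact test, and a p above the threshold does not show that the shares are equal.

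Fibroblast, epithelial, neuron, muscle, homeobox and hepatocyte genes were marked less often than other genes, and endothelial genes did not pass the test. Of these calls, that of the hepatocyte list alone ended against random lists matched on promoter CpG content (9.52% against 19.1%), a comparison chosen after seeing the data. None of 25 fibroblast and stromal genes was marked in both replicates (adjusted exact p = 1.3e-05), although 2 had a peak in replicate 2, and Acta2 and Bglap had a peak in neither. None of 18 epithelial genes (adjusted exact p = 2.9e-04), 22 neuron genes (5.2e-05) or 22 skeletal and cardiac muscle genes (5.2e-05) had a promoter peak in either replicate, Cdh1, Cldn3, Camk2a, Dcx, Acta1 and Actc1 among them. For a list of 22 genes a share of 0 has an upper 95% Wilson limit of 14.9%. Of 30 homeobox developmental regulators 1 was marked (3.33%, adjusted exact p = 3.3e-05), and Dlx1 and Dlx2 were not. Of the hepatocyte genes 2 of 21 were marked (9.52%, adjusted exact p = 0.00997), the clotting factor gene F9 (10.5 and 10.3) and the apolipoprotein gene Apoa2 (5.62 and 6.37), whereas the albumin gene Alb and Ahsg were not. Of 18 endothelial genes 5 were marked (27.8%, adjusted exact p = 0.39), including Pecam1, an adhesion molecule gene whose start lies within 1 kb of another (33.6 and 32.5), Cdh5, Eng (6.20 and 5.70) and Kdr (5.68 and 6.37), while Cldn5 and Egfl7 were not.

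Genes of other blood lineages were marked less often than other genes in 4 of 6 lists, with some members high in their list. All 4 calls ended against random lists matched on promoter CpG content, a comparison chosen after seeing the data. Neutrophil genes were marked in 4 of 23 cases (17.4%, adjusted exact p = 0.0473): Csf3r, the receptor for granulocyte colony-stimulating factor (16.2 and 16.9), Prtn3, which shares its promoter with another gene (15.7 and 12.8), Cebpe (6.71 and 8.38) and Mmp8 (4.47 and 2.80), but not Camp or Ctsg. The Mmp8 peaks with these folds do not overlap, lying at 7558515 to 7558993 in replicate 1 and 7557254 to 7557780 in replicate 2. B cell genes were marked in 3 of 22 cases (13.6%, adjusted exact p = 0.0225): Bank1 (19.4 and 19.9), Vpreb1, whose start lies within 1 kb of another (9.46 and 9.39), and Ms4a1, which encodes CD20 (6.37 and 4.86). Blk had no peak. At Bach2, a transcription factor gene of this list, a replicate 2 peak (fold 16.3) reached the window while the replicate 1 peak that overlaps it did not. T and NK cell genes were marked in 4 of 26 cases (15.4%, adjusted exact p = 0.0225): Cd28 (21.5 and 22.3), Il7r (20.8 and 18.3), Cd3d (8.30 and 9.89) and Lck (4.47 and 4.69), but not Bcl11b or Cd2. Mast cell and stem cell genes were marked in 2 of 20 cases (10.0%, adjusted exact p = 0.00997), Fli1 (27.2 and 32.01) and Meis1 (5.43 and 4.51), and neither Cd34 nor Cma1 was. Dendritic cell genes were marked in 5 of 22 cases (22.7%, adjusted exact p = 0.16; 8 in replicate 2), led by Bst2, Tcf4 (25.8 and 26.6), the chemokine receptor gene Xcr1 (23.6 and 20.0) and Clec10a, with no peak at Batf3 or Ccr7. Erythroid and megakaryocyte genes were marked in 4 of 21 cases (19.05%, adjusted exact p = 0.099): the platelet chemokine gene Pf4 (41.6 and 42.6), Tal1 (12.6 and 14.9), the transferrin receptor gene Tfrc (6.88 and 5.70) and Nfe2 (5.85 and 6.03), but not Alas2 or Epor. The Tfrc peaks with these folds do not overlap, lying at 32609324 to 32609977 in replicate 1 and 32607923 to 32608827 in replicate 2.

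In all, 8 of 26 lists were marked more often than other genes, 10 less often, and 8 passed the threshold in neither direction (Fisher's exact test, two-sided, Benjamini-Hochberg over 26 lists; genes are not replicates, so p describes these libraries). The call of the neutrophil list ended with a 2.5 kb window (share 21.7%, adjusted exact p = 0.126) and without genes that share a promoter (share 13.6%, adjusted exact p = 0.104), against a share of 17.4% in the main test. That of the T and NK cell list ended without such genes (share 16.7% against 15.4%, adjusted exact p = 0.125). Over 10 alternatives the adjusted p ranged from 0.00394 to 1 for neutrophil genes and from 5.9e-04 to 0.362 for T and NK cell genes. With the gene's 5′ end alone in place of all starts, the share was 3.85% for T and NK cell genes, 26.7% for liver macrophage genes, which is below the share of all genes, and 16.7% for endothelial genes. The peaks given for Arhgap22, Csf1r, Prtn3, Tcf4, Clec10a, Cd28, Cd3d, Lck, Cdh5 and Mef2c lie over 1 kb from the gene's 5′ end, near another annotated start. Within 500 bp of a start the share was 8.70% for neutrophil and 4.76% for hepatocyte genes. With a 2.5 kb window it was 9.09% for muscle genes. Dendritic cell genes reached 36.4% without replicate 1, 45.5% in the replicated list and 54.5% in the pooled pseudoreplicated list. The same shares of fibroblast genes were 8%, 8% and 4%. Against random lists matched on promoter CpG content, a comparison chosen after seeing the data, the calls of the neutrophil, B cell, T and NK cell, mast cell and stem cell, and hepatocyte lists ended, with permutation adjusted p from 0.0887 to 1. Erythroid and megakaryocyte genes passed the threshold as lower in the replicated list (adjusted exact p = 0.038, range over 10 alternatives 0.0378 to 0.902) and liver macrophage genes as higher against CpG-matched lists (permutation adjusted p = 0.0472, range 0.0472 to 1).

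**Figure D3:**
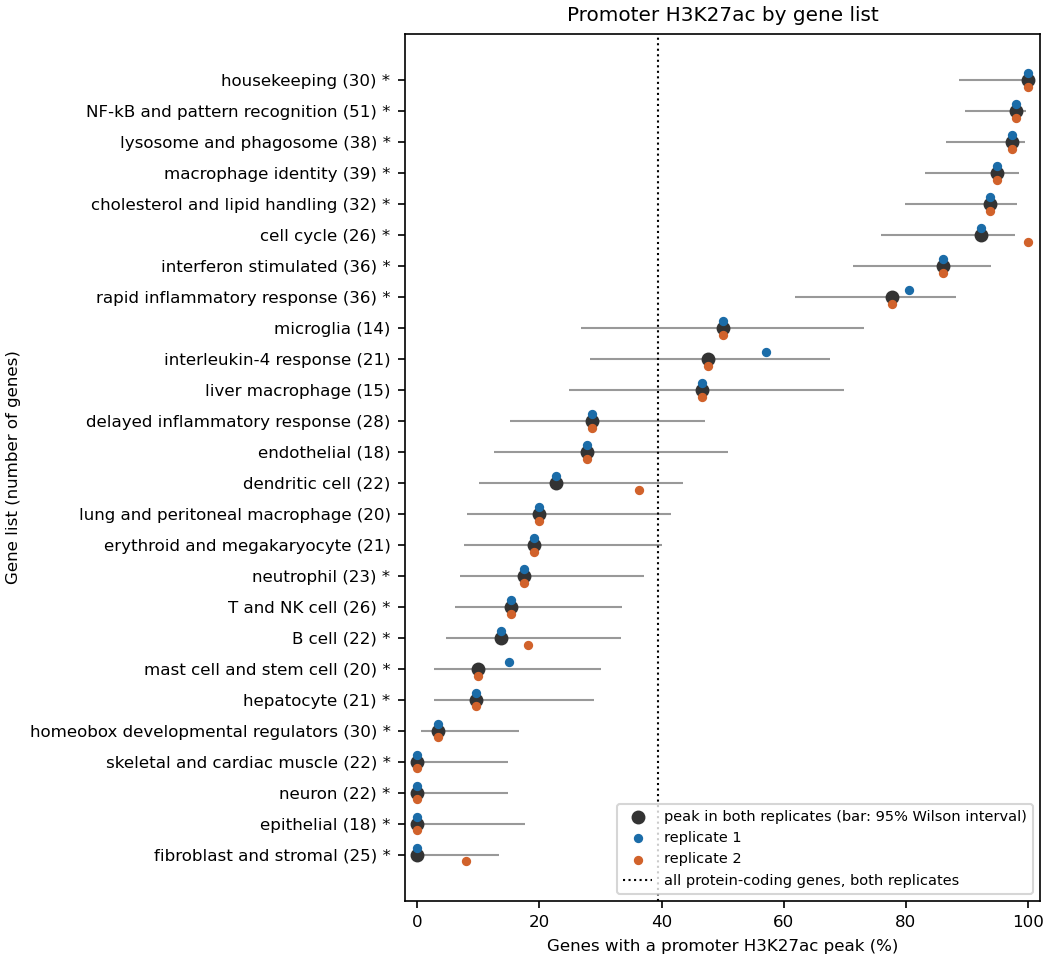
Share of genes with a promoter H3K27ac peak (%, horizontal axis) for each of 26 gene lists (vertical axis, number of genes in parentheses): black points, peak in both replicates with 95% Wilson interval; blue and orange points, replicates 1 and 2; dotted line, all protein-coding genes (39.4%); asterisk, adjusted p under 0.05 in Fisher's exact test. Shares run from 0% for 4 lists of other tissues to 100% for housekeeping genes.

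Macrophage identity genes and 8 other lists had more distal peaks nearby than random lists. Macrophage identity genes had a mean of 2.77 distal peaks within 25 kb of the 5′ end, against 0.878 in random lists with the same number of marked genes, and 36 of 39 had at least 1; Mrc1 had 7 and Itgam 6. The interleukin-4 response list (1.76 against 0.550), the rapid inflammatory list (1.86 against 0.758), the delayed inflammatory list (1.25 against 0.421) and the NF-kB and pattern recognition list (1.76 against 0.897) also lay above their random lists, all with a permutation p of 0.0002, the smallest that 10000 lists can give (adjusted p = 0.00104). Lysosome and phagosome genes (1.84 against 0.897) and cholesterol and lipid genes (1.81 against 0.869) followed, with an adjusted permutation p of 0.00223 each. Then came microglia genes (1.71 against 0.568, adjusted p = 0.00585 by permutation) and lung and peritoneal macrophage genes (1.10 against 0.363, adjusted p = 0.00867 by permutation). The lung and peritoneal mean rests on few genes. Only 7 of these 20 genes had at least 1 distal peak, the median was 0, and Cd9, Pparg, Cd5l and Serpinb2 had 4 each. In each of the other lists above their random lists, 53.6% or more of the genes had at least 1. Genes without a promoter peak could hold several distal ones: Acod1, Cxcl1, Atp6v0d2, Cd5l, Batf3, Ankdd1a and the skeletal muscle actin gene Acta1 had 4 each, and Cxcl2 and Alox15 had 3.

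The other 17 lists passed the threshold in neither direction in the two-sided permutation test with Benjamini-Hochberg adjustment over 26 lists. Interferon stimulated genes, most of them marked at the promoter, had 0.833 distal peaks per gene against 0.821 in random lists, cell cycle genes 0.577 against 0.855 and housekeeping genes 1.5 against 0.910 (adjusted permutation p = 0.0900). The means of the blood lineages were 0.773 for dendritic cell genes, 0.591 for B cell, 0.385 for T and NK cell, 0.348 for neutrophil, 0.333 for erythroid and megakaryocyte, and 0.2 for mast cell and stem cell genes, against 0.294 to 0.378 in their random lists. Liver macrophage genes had 0.867, endothelial genes 0.667, skeletal and cardiac muscle genes 0.364, epithelial genes 0.333, fibroblast and stromal genes 0.160, hepatocyte genes 0.143, neuron genes 0.0909 and homeobox regulators 0.0667. With replicate 2 alone, without replicate 1, the homeobox list had a mean of 0 and passed as lower (adjusted permutation p = 0.0260, range over 6 alternatives 0.0187 to 0.515). With each peak counted for the nearest 5′ end alone, chosen after seeing the data, the delayed inflammatory list kept its call at 0.714 (adjusted permutation p = 0.0335, range 0.00104 to 0.0335 over 6 alternatives). In that count the means were 0.933 for housekeeping, 0.528 for interferon stimulated, 0.409 for dendritic cell and 0.231 for cell cycle genes. Without replicate 1 the means were 0.565 for neutrophil, 0.35 for mast cell and stem cell, and 0.182 for muscle genes. The lysosome and phagosome call ended at a distance of 100 kb (adjusted permutation p = 0.130, range 7.4e-04 to 0.130 over 6 alternatives), and the lung and peritoneal call ended against unmatched random lists (0.0797, range 0.00520 to 0.0797).

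**Figure D4:**
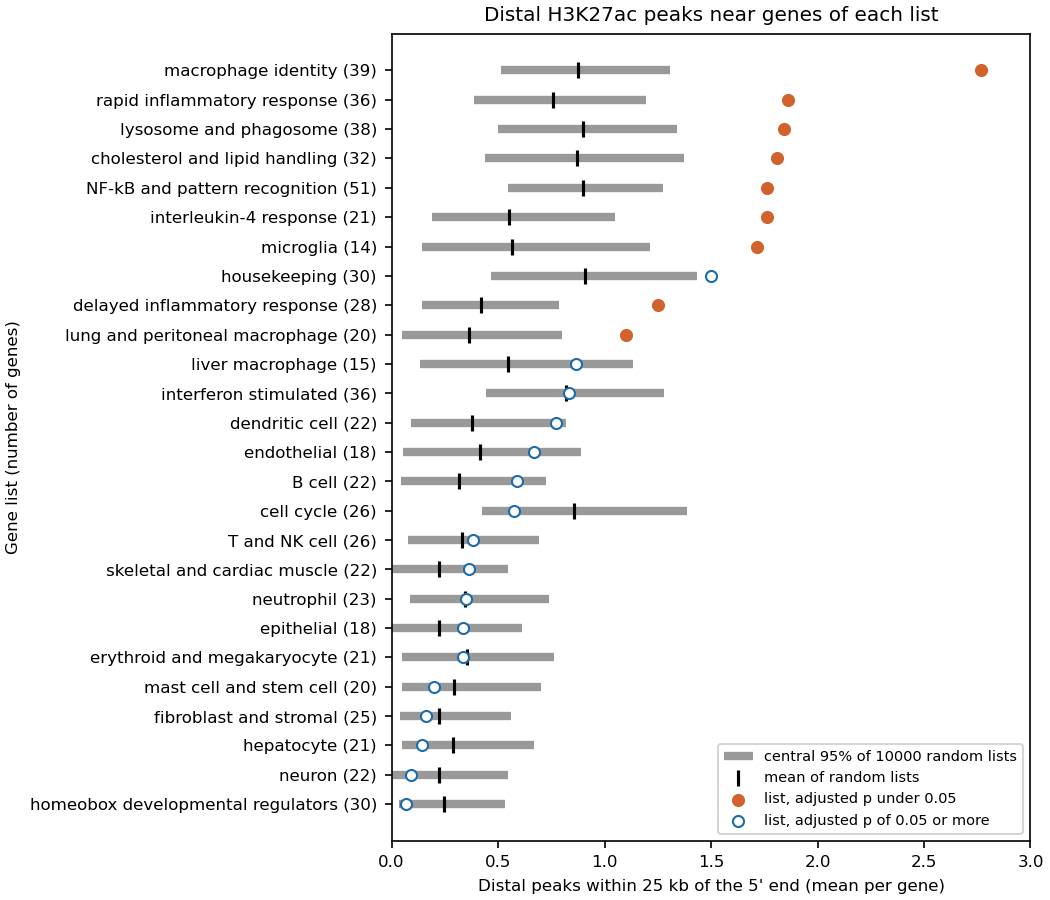
Mean number of distal H3K27ac peaks found in both replicates within 25 kb of the 5′ end (horizontal axis, peaks per gene) for each gene list (vertical axis, number of genes in parentheses); grey bars are the central 95% of 10000 random lists with the same number of marked genes, ticks their mean, and filled orange points lists with an adjusted permutation p under 0.05. Macrophage identity genes lie farthest to the right, at 2.77 peaks per gene.

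Clusters of distal peaks were ranked by the length they covered in the replicated list, a single list without replicate error. Its 19108 distal peaks formed 10885 clusters, of which 345 covered 10 kb or more. The longest lay on chromosome 8 at 126824206 to 126930385, with 16 peaks covering 55540 bp (50484 and 50790 bp in the replicates); the nearest 5′ end was that of Tomm20, a mitochondrial import receptor gene, 68548 bp from its midpoint. The 10 longest also included clusters nearest to Atf3, a stress-induced transcription factor gene (41350 bp), Zfp36l2, an RNA decay factor gene (40140 bp), the ceramide kinase gene Cerk (33945 bp), Eya3 (32320 bp), Incenp (31227 bp), the survival gene Bcl2l1 (30997 bp), Ankdd1a (30067 bp) and Apbb1ip, an adaptor of integrin activation (28836 bp). The Ankdd1a cluster overlapped Plekho2, and Ankdd1a was the only nearest gene of the 10 without a promoter peak in either replicate. Nearness does not show which gene a cluster acts on.

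Distal peaks were enriched for sequence words of macrophage transcription factors. The PU.1 word GAGGAAGT occurred in 9.90% of 15068 distal peaks and in 2.94% of 24402 flanking sequences, a ratio of 3.36, above all 279 reorderings of its letters. The AP-1 (1.95) and RUNX (1.39) ratios also lay above all reorderings. The ratios of C/EBP (1.07), IRF (2.46), MITF/TFE (2.47) and MAF (1.56) passed the threshold with some reorderings above them, at percentiles of 99.7, 99.6, 98.1 and 97.3, and that of MAF lay inside the central 95% of its reorderings. The adjusted p in the one-sided exact rank test over 12 words was 0.00959 for PU.1, AP-1, RUNX and C/EBP, 0.00999 for IRF, 0.0343 for MITF/TFE and 0.0420 for MAF. The C/EBP ratio, though past the threshold, rests on shares of 38.2% and 35.6%. Of the words fixed as controls from other lineages, MEF2 was enriched (1.44, adjusted p = 0.00959 by the exact rank test), so enrichment was not limited to the words chosen for macrophage factors. The gene Mef2c was itself marked (28.4 and 25.8), so MEF2 is a poor control here. GATA (0.870), HNF4 (1.05) and REST (1.34) were not enriched, and neither was NF-kB (1.28, adjusted p = 0.542 by the exact rank test). The 8 calls were also made in each replicate alone. Peaks had a GC content of 46.5% and flanks of 44.4%. A reordering keeps the letters of a word but need not keep a CpG in it, and peaks and flanks were not matched on CpG content. That limits the MITF/TFE call, whose word holds a CpG, and the IRF, C/EBP and MAF calls, whose words can hold one.

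**Figure D5:**
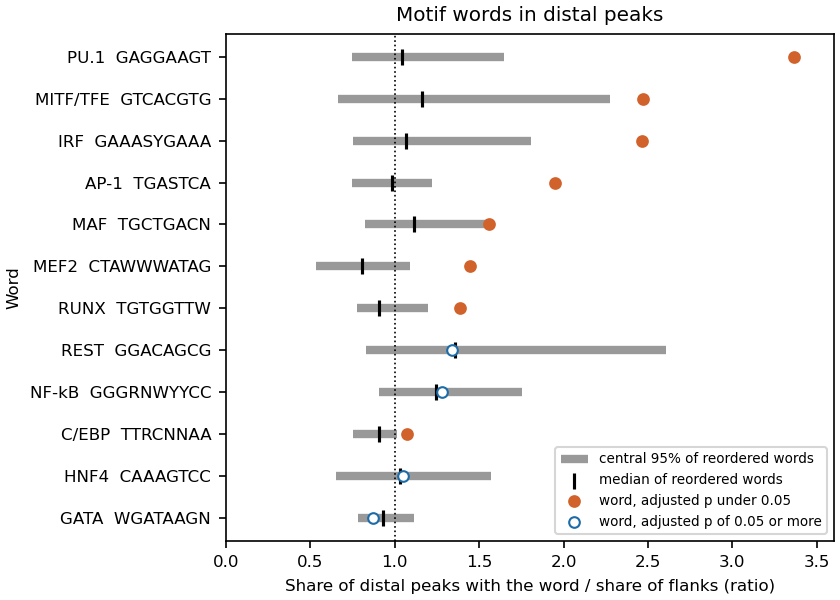
Ratio of the share of distal peaks with a word to the share of flanking sequences with it (horizontal axis) for 12 words (vertical axis); grey bars are the central 95% of reorderings of the word's letters, ticks their median, filled orange points words with an adjusted p under 0.05 in the exact rank test. PU.1 has the highest ratio, 3.36.

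Sex chromosomes carried fewer peaks per length than autosomes. The X chromosome had 4.35 and 4.19 peaks per Mb, against 11.7 and 11.6 on autosomes, and the Y chromosome had 2 peaks in each replicate. Xist, the RNA gene that silences an X chromosome in female cells, had a peak within 1 kb of its 5′ end in both replicates (18.1 and 17.4), lying at 103480887 to 103483165 inside the gene in replicate 1. Of the Y-linked genes, Uty had a promoter peak in both replicates (3.96 and 4.36), Ddx3y only in the lists made from both libraries (3.25), and Kdm5d and Eif2s3y in none. The labels state that the sex of the mice was not collected.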

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

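Random lists matched on CpG content, distal peaks counted for the nearest 5′ end, and single replicates for the number of peaks and the sex chromosomes were chosen only after the results were seen; the other alternatives were fixed earlier. The mean share of peaks found in the other replicate was 78.4% when 50% of both peaks had to overlap, against 89.9%, which is a stricter definition. It was 91.9% among the 20000 peaks with the highest fold. Both lists were cut for that share, so a peak can lose a partner that lies below the cut of the other list. The 91.9% is therefore not directly comparable with the 89.9%. The promoter share was 45.9% with a 2.5 kb window, which is wider by construction. The X chromosome had 4.04 peaks per Mb at a −log10 q of at least 5, against 4.27, since fewer peaks were counted. The number of lists marked less often than other genes was 5 against lists matched on CpG content, in place of 10, and 8 to 11 under the other alternatives, while 8 lists were marked more often under all alternatives fixed earlier and 9 against CpG-matched lists. The number of lists with fewer distal peaks than random lists was 1 with unmatched random lists and ranged from 0 to 1 when either replicate was left out, against 0; in both cases it was the homeobox regulators, and the cause was not tested. Lists with more distal peaks numbered 9 or 10 throughout.

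Of single-list results, 249 for promoters kept their call or lack of one across 10 alternatives, 8 lost it and 3 gained one; for distal peaks 149 kept it across 6 alternatives, 2 lost it and 5 gained one. At 100 kb, dendritic cell genes (adjusted permutation p = 0.00416, range 0.00416 to 0.515) and liver macrophage genes (0.0432, range 0.0432 to 0.508) gained a call, as housekeeping genes did against unmatched lists (7.4e-04, range 7.4e-04 to 0.352). All 36 results for motif words were the same, and 7 or 8 of the 10 longest clusters stayed among the 10 longest with a joining distance of 5 kb or from a single replicate. No result reversed. Leaving out a replicate gives no value for the overlap of replicates or for sharing by rank, which need both lists, and with 1 library on each side those comparisons have no test. No paired analysis was possible because the series has a single group. The depth of the libraries is unknown, so low peaks found in a single replicate, of which 83.4% and 80.1% were in the replicated list, cannot be read as differences between the replicates.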

Other observations

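The gene families, noncoding genes and single genes of this and the next paragraph, the lists matched on CpG content, the test of the 5 lists that kept their call against them, and the test of distal peaks counted once were chosen only after the results were seen. Of 30 gene families taken by symbol, 7 were marked at promoters more often than other genes and 12 less often (Fisher's exact test, two-sided, adjusted over the families). The families were not set against random lists matched on promoter CpG content. Its part in these calls was therefore not tested, and it may account for some of them. Ribosomal protein genes were marked in 78 of 82 cases (95.1%, adjusted exact p = 5.1e-26), proteasome subunits in 37 of 40 (92.5%, adjusted exact p = 8.6e-12), including the immunoproteasome genes Psmb9, which has another gene's start within 1 kb (24.8 and 26.8), and Psmb10 (24.6 and 25.6), and histone genes in 57 of 67 (85.1%, adjusted exact p = 1.3e-13), some of whose clustered copies share a peak. All 12 genes with a Cxcl symbol (adjusted exact p = 0.00773) and all 14 type I interferon genes (adjusted exact p = 0.00266) were without a promoter peak in both replicates, although Pf4, a CXC chemokine gene under another symbol, was marked (41.6 and 42.6). Of the CC chemokine genes, 8 of 23 were marked, including Ccl3 (38.0 and 33.8), Ccl4 (28.7 and 27.3) and Ccl9 (25.5 and 25.5), and that list did not pass the test (adjusted exact p = 0.83). Only 5 of 33 interleukin genes were marked (15.2%, adjusted exact p = 0.00637): Il15, Il18, which has another gene's start within 1 kb, Il10, Il16 and Il27. Sialic acid receptors were marked in 4 of 7 cases without passing the exact test (adjusted exact p = 0.55), with Siglec1 (46.3 and 48.1) and Cd33 (29.0 and 26.1) highest. Cathepsin genes were marked in 11 of 18 cases, Ctsb, Ctsd (44.1 and 43.1) and Ctsz (38.6 and 39.2) at the top, and did not pass the test either (adjusted exact p = 0.13).

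Olfactory receptor genes were marked in 8 of 1135 cases, with Olfr111 (31.2 and 29.8) above the next, Olfr550 (13.8 and 15.9). Vomeronasal receptors were marked in 1 of 329 cases, and no keratin, beta-defensin, Wnt or fibroblast growth factor gene was marked in both replicates. Among noncoding genes, 364 of 5470 long intergenic RNA genes (6.65%) and 94 of 1856 microRNA genes were marked, and Neat1, the scaffold RNA of paraspeckles, had folds of 49.4 and 50.1 at a peak that it shares with the start of an antisense gene. The genes with the most distal peaks within 25 kb were Ctsk, the protease of osteoclasts, Cyth4 and Ttc7b, with 10 each, followed by genes with 9 that include Cd300a and Ctss, which lies next to Ctsk. Among genes without a promoter peak in either replicate, Nanos3 had 8 such peaks and Egr3, a transcription factor gene, had 7. Ranked by the narrower of the replicates, the broadest promoter peaks spanned 16230 and 16824 bp at Vps13d, 16346 and 16079 bp at the shedding protease gene Adam8 and its neighbour 6430531B16Rik, which share the peak, 16207 and 15542 bp at Sh3gl1, and 14470 and 17780 bp at Ctsb.

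Delayed inflammatory genes without a promoter peak lay near more distal peaks than other unmarked genes: the 20 genes had a mean of 0.9, against 0.211 in random unmarked lists (central 95% 0 to 0.550, permutation p = 0.0022). Distal peaks nearest to a marked gene do not account for all of it, since the mean was 0.850 without them (random 0.156, permutation p = 0.0010). Nearness does not show which gene a peak acts on, and the random lists were not matched on marked neighbours. Other effects of marked neighbours therefore stay open. Missed promoter peaks may account for part of it, since Serpinb2 and Fpr2, with 4 and 3 counts, had a peak within 2.5 kb. The 18 members without such a peak had a mean of 0.611 (random 0.170, central 95% 0 to 0.5, permutation p = 0.0182). Among these 18, Acod1 and Fpr1 hold 4 and 3 counts. Peaks counted for neighbouring members, as at Fpr1 and Fpr2, do not account for all of it, with a mean of 0.750 when each was counted once (permutation p = 0.0092). The pattern rests on few genes: Serpinb2 and Acod1 with 4 peaks each and Fpr1 and Fpr2 with 3 each hold 14 of the 18 counts, and 12 of the genes had none. The pattern may not be particular to delayed genes. Of the 7 rapid inflammatory genes without a promoter peak in either replicate, Egr3 had 7 distal peaks, Cxcl1 had 4 and Cxcl2 had 3. Those 7 genes were not tested as a set, and the counts of the others are not given. That some delayed genes may keep acetylated distal elements before stimulation remains a hypothesis found and tested on the same data, and since the series has a single group no biological explanation was tested.

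Peaks at Xist and at the Y-linked gene Uty stood in both replicates, although Xist is known to be active in female cells and Uty in male cells. Reads shared with copies of the Uty promoter are argued against, since 0% of the 618 words of 31 bases in the Uty peak occur elsewhere in the genome. Whether the Xist peak belongs to another gene's start remains open. The criterion set beforehand for that explanation, a nearer start of another gene, was met: the midpoint in replicate 1 lay 1228 bp from the Xist 5′ end and 1080 bp from the start of Gm27520. That gene is a small RNA annotated inside Xist, and only after the result was seen was the test read as undecided for that reason. Cells from mice of both sexes in each library may also give such peaks, which was not tested, and a promoter peak does not show transcription.

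Promoter CpG content differs between lists and goes with marking, from 6.52% of genes marked in the lowest decile to 68.6% in the highest. It is not the whole cause for the lists marked more often, since 8 of 8 kept their call against lists matched on CpG content. Macrophage identity genes were marked in 94.9% of cases against 28.4% in matched lists. It may account for part of the excess: cell cycle genes were marked in 92.3% against 59.7% in matched lists, which is above the 39.3% of other genes. CpG content was measured within 500 bp of the gene's 5′ end alone, while marking counted any annotated start. For the 10 lists marked less often the result is divided, with 5 keeping their call. Those 5, the fibroblast, epithelial, neuron, muscle and homeobox genes, were singled out because they kept it. A test of them as a set therefore had a fixed outcome and adds nothing. The adjusted permutation p of each list, taken over the 26 lists, was 0.0044 or less. For each of them that argues against CpG content as the whole cause, homeobox genes being marked in 3.33% against 55.6% in matched lists. Neutrophil genes were marked in 17.4% against 17.2% in matched lists (central 95% 4.35 to 34.8%), so CpG content can account for that difference. For the rest of the lists that lost their call it stays open, and it may account for part of the difference. B cell genes were marked in 13.6% against 22.6% in matched lists (central 95% 9.09 to 40.9%). Mast cell and stem cell genes were marked in 10.0% against 29.0% (central 95% 10.0 to 45.0%).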
